A study of Homo sapiens with 6 samples.

How the data were processed

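RNA sequencing libraries from human umbilical vein endothelial cells were compared in 2 groups of 3, untreated and nanosilicate-treated, as the sample titles name them. The deposited table holds 1 RPKM column per library, scaled by the authors to gene length and library total. The submitters' processing notes name bcl2fastq, STAR and hg38, without versions or roles. They were taken here as the tools for demultiplexing and alignment and as the genome build. The read counter, the annotation and the filter on low values are not given in the sources used here. Columns were matched to samples by name, and the columns that carry no treatment in their name were taken as the untreated samples.

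The table lists 11386 genes, with no value at 0 and a lowest value of 0.322 RPKM. Every gene has at least 2 libraries at 1.001 RPKM or more, so genes below that level in nearly all libraries are not listed and were not analysed here. No mitochondrially encoded gene and no member of the list of nuclear-retained RNAs was listed, so those lists, which would show RNA quality, had 0 members. RPKM ratios between libraries were ratios of whole reads for 11385 genes (99.99%, at a ratio tolerance of 1e-12). This gave library totals of 45476807 to 89903501 reads, of which 97.27% to 97.44% fell in listed genes. The 10 most abundant genes took 6.78% to 7.7% of reads. The recovered gene lengths were multiples of 3 for 83.4% of genes and equalled the longest coding sequence of GENCODE 29 plus stop for 63.1%, so they are coding lengths. For 91 genes the length was over 3 times the coding length, 72 of them on chromosome 6 between 28 and 34 megabases, so RPKM levels there are understated, which also shrinks fold changes on the log2(RPKM + 1) scale and can put genes below the filter. Replicates were not duplicates: read counts of pairs within a group differed by a chi-square per degree of freedom of 10.5 to 45.2.

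The main test was limma (3.58.1, R 4.3.3) on log2(RPKM + 1) with an intensity trend, on 11340 genes with at least 1 RPKM in at least 3 libraries. It was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates changes of low genes. Gene lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move on balance in 1 direction and compares them with no other genes. Of 38 lists fixed before the data were examined, 34 could be tested. The named genes were chosen by a rule set at the same time. It took 13 fixed genes (LEF1 was not listed), the 10 largest called changes in each direction with a mean of at least 2 RPKM and no overlap between groups, and up to 4 members of each list with the smallest adjusted p. Gene positions and coding GC content come from GENCODE 29 (GRCh38), which gave a GC value for 11358 genes (99.75%). Symbols and Entrez identifiers are those of the deposited table. A gene that the rule names is not reported here, though counts and list tests include it.

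The steps were tested on simulated data made from the real means and spreads. For the comparison of nanosilicate with untreated cells, 11324 genes were run. The fit recovered 32% of genes changed 1.2-fold, 85.7% changed 1.5-fold and 100% changed 2-fold or 3-fold, with 9 false calls among 167. Simulated genes were drawn independently, without a GC trend or other shared library effect. The share of false calls may therefore not hold for the real libraries. Alternatives set before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter at 5 RPKM, median-of-ratios scaling, quantile normalization, no trend, robust moderation, library weights, the replicate number as a block, each library left out, an adjusted p of 0.01 and a fold of 1.5. Added after the data were seen were a GC correction by local regression per library (span 0.3), the same with coding length, the GC correction with the block, and limma-voom on the recovered reads. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the tables and plots.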

Results

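Transcript levels were measured by RNA sequencing in human umbilical vein endothelial cells (HUVEC), primary cells taken from the inner lining of the vein of the umbilical cord. The 6 libraries fell into 2 groups. Untreated cells gave 3 libraries, and cells exposed to nanosilicates, mineral particles of nanometre size, gave the other 3. The particles were given at 10 µg/mL for 48 hours and washed off, growth went on for 5 days, and RNA was taken on day 7, so the levels describe cells days after the exposure ended. The deposited values were RPKM, read counts scaled to gene length and library total. Library totals recovered from the steps of those values were 58873776, 62728494 and 89903501 reads for the untreated libraries and 45476807, 63935145 and 49152524 reads for the treated ones. The median gene had between 1312 and 2558 reads per library. The table listed 11386 genes, and 11340 with at least 1 RPKM in at least 3 libraries were tested. Nothing in the labels says that libraries of a group came from separate cultures or donors, so the p-values measure the spread between these libraries, which may be technical.

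The comparison of treated with untreated cells asks which transcripts differ after nanosilicate exposure, and the series title names oxidative stress, Wnt/β-catenin signalling and angiogenesis. KRT7, an intermediate filament keratin, fell from 68.9 ± 3.20 to 37.1 ± 4.07 RPKM (SD, n = 3 per group), a log2 fold change of -0.88 with a standard error of 0.07. INHBA, which encodes a subunit of activin, fell from 8.78 ± 0.69 to 4.69 ± 0.12 RPKM. In the other direction, LYVE1, a hyaluronan receptor of lymphatic endothelium, rose from 41.7 ± 2.66 to 68.1 ± 10.4 RPKM, and AQP1, a water channel, rose from 153 ± 10.5 to 201 ± 11.9 RPKM. In all, 129 genes passed an adjusted p of 0.05 in limma's moderated test with Benjamini-Hochberg adjustment, 21 of them higher and 108 lower with nanosilicates, and 2138 genes had an unadjusted p under 0.05. Higher genes were 16.3% of the calls, against 25.6% after a correction for GC content that was added after the data were seen (23 higher, 67 lower) and 45.2% with library weights (471 higher, 571 lower). Leaving out 1 library at a time moved the counts from 1 higher and 16 lower genes without nanosilicate replicate 1 to 351 higher and 430 lower without nanosilicate replicate 2, with 1 and 38 without untreated replicate 1, 2 and 16 without untreated replicate 2, 17 and 170 without untreated replicate 3, and 3 and 22 without nanosilicate replicate 3.

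The first principal component of the log2 values held 49.4% of the variance and placed the untreated libraries at -11.84, -6.68 and -2.39 and the treated ones at 8.14, 2.83 and 9.95. The libraries also differed in how their values depended on the GC content of a gene's coding sequence. The slopes were 0.07, 0.04 and 0.0025 log2 units per 10 percentage points of GC in the untreated libraries and -0.06, -0.0067 and -0.05 in the treated ones. Every untreated slope lay above every treated slope, for which an exact permutation test gave p = 0.1 (two-sided), the smallest p that 3 against 3 allow. Across genes, which are not independent replicates, the log2 fold change had a Pearson correlation of -0.497 with GC content. The median GC content was 51.9% over all tested genes, 62.5% for those that fell and 50.3% for those that rose.

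**Figure D1:**
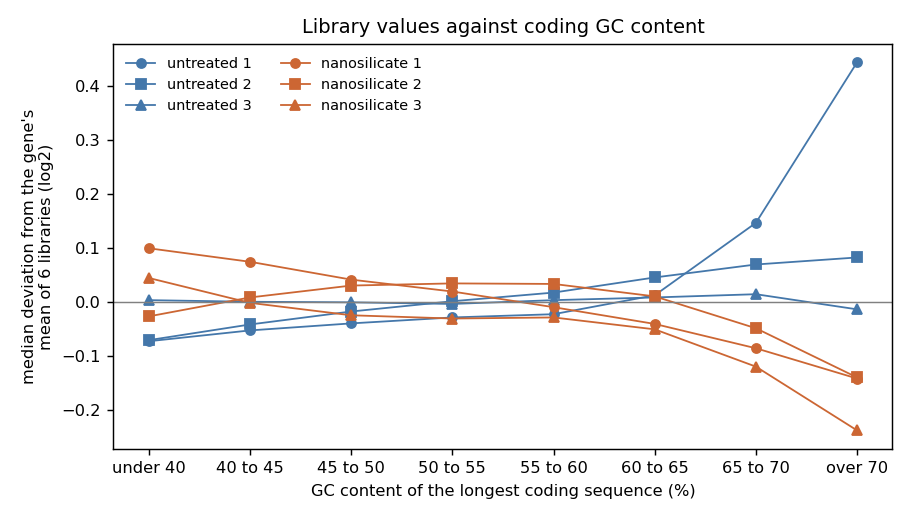
Median deviation of each library from the gene's mean over the 6 libraries (y axis, log2 units) for genes grouped by the GC content of their longest coding sequence (x axis, percent); each line is 1 library, blue for untreated and orange for nanosilicate. Above 70% GC the untreated libraries sit at 0.44, 0.08 and -0.013 and the treated ones at -0.14, -0.14 and -0.24.

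Among the 10 genes with the largest increases, LYVE1 (Entrez 10894, chromosome 11, 10556966 to 10611689 in GRCh38) led with a log2 fold change of 0.68 ± 0.09 (SE, adjusted p = 0.0159). ENTPD1 (CD39, which breaks down extracellular ATP) rose from 51.6 ± 4.50 to 66.9 ± 3.94 RPKM (adjusted p = 0.0365). UCP2, an uncoupling protein of the inner mitochondrial membrane, rose from 7.01 ± 0.24 to 9.16 ± 0.29 RPKM (adjusted p = 0.0287). C10orf128, CST1, MYZAP, PRICKLE4, GSTM2, AQP1 and SYNE2 completed this group, with log2 fold changes from 0.35 for SYNE2 to 0.46 for C10orf128. LYVE1, AQP1, ENTPD1, MYZAP, PRICKLE4, GSTM2 and SYNE2 overlap other coding genes in the annotation, as do KRT7, TAGLN and MAFF among the decreases, and GSTM2 and CST1 have close paralogs, so reads may have been shared in the authors' counting. After the GC correction, SYNE2 no longer passed (adjusted p = 0.069), with a log2 fold change of 0.31 ± 0.07 against 0.35 ± 0.07 before (SE).

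Among the 10 largest decreases, TMEM158 (chromosome 3, 45224466 to 45226278) had the lowest log2 fold change at -1.003 ± 0.17 (SE, adjusted p = 0.0287), which became -0.55 ± 0.11 after the GC correction, its coding sequence being 77.4% GC. KRT7 (Entrez 3855, chromosome 12, 52232520 to 52252186) and INHBA (Entrez 3624, chromosome 7, 41667168 to 41705834) had the smallest adjusted p, 0.0017 for each. COL12A1, a fibril-associated collagen, fell from 16.3 ± 2.67 to 8.45 ± 1.19 RPKM. TGFB2, a TGF-β ligand, fell from 3.32 ± 0.22 to 1.55 ± 0.33 RPKM, and TAGLN, an actin-binding protein of contractile cells, fell from 10 ± 0.88 to 5.63 ± 0.66 RPKM. AK4, a mitochondrial adenylate kinase, fell from 10.7 ± 0.77 to 6.16 ± 0.46 RPKM. TNFRSF6B, a decoy receptor that shares its locus with a readthrough transcript, fell from 32.8 ± 5.28 to 19.1 ± 1.54 RPKM. MAFF, a small MAF transcription factor, and NRARP, a feedback regulator of Notch, fell with log2 fold changes of -0.75 ± 0.15 and -0.72 ± 0.14 (SE). After the GC correction they were -0.48 ± 0.10 and -0.57 ± 0.12 and no longer passed (adjusted p = 0.0552 and 0.058).

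**Figure D2:**
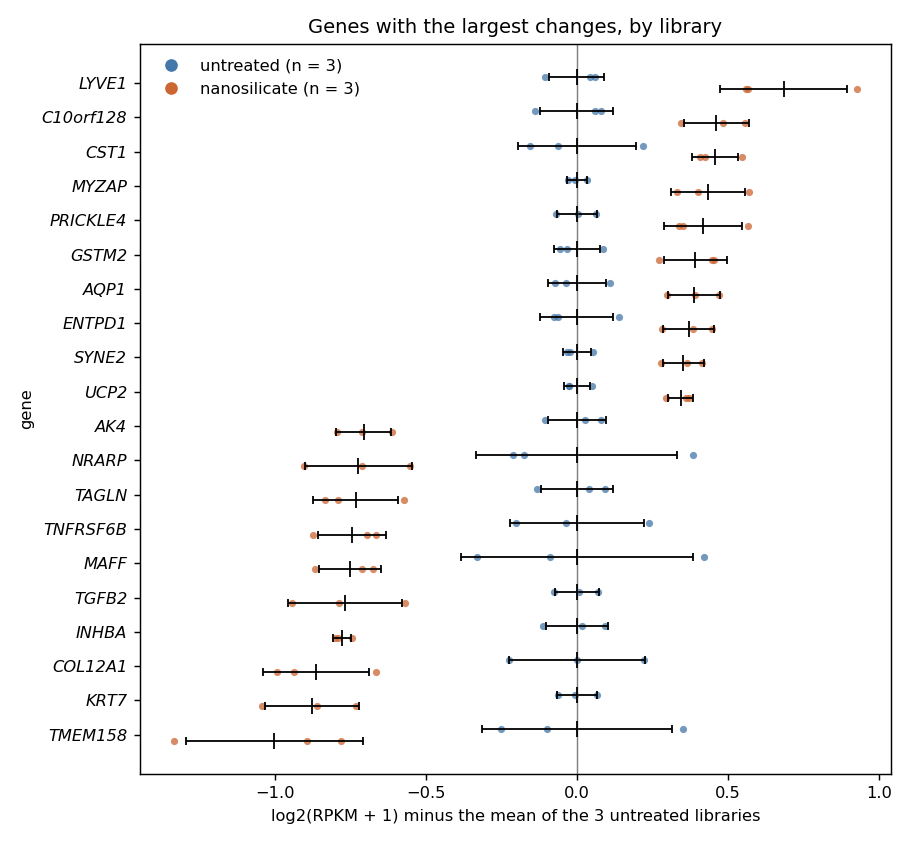
log2(RPKM + 1) of each library minus the mean of the 3 untreated libraries (x axis, log2 units) for the 10 genes with the largest increases and the 10 with the largest decreases (y axis); points are libraries, and black marks give the group mean with its SD. LYVE1 lies highest, with a mean difference of 0.68, and TMEM158 lowest, with -1.003.

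Gene lists fixed before the data were examined were compared with all other genes by camera, with a preset inter-gene correlation of 0.01. Lists share members, such as SLC2A1 in the Wnt target and hypoxia lists, so their counts are not independent. Of 34 lists tested, 19 were lower and 1 was higher at an adjusted p under 0.05. With an estimated correlation 0 passed, and the lowest adjusted p was 0.258. The Wnt ligand, lysosome and metal response lists lost the call too, with estimated correlations of -0.045, -0.012 and -0.015. The losses thus do not by themselves show that correlation between genes made the calls. With fry 0 lists were higher and 5 lower. Those 5 were Wnt ligands, receptors and secreted regulators (adjusted p = 0.00344), lysosome and autophagy (0.0171), hypoxia and glycolysis (0.046), matrix proteases (0.046) and TGF-β response (0.046). After the GC correction fry gave 0.0463 for each of these 5 and for the metal response list (0.0571 before). Other splits of the same 6 libraries called up to 19 lists with camera at the preset correlation.

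Wnt/β-catenin target genes were lower as a list at the preset correlation (camera adjusted p = 1.13e-06), but not with an estimated correlation (adjusted p = 0.258) or with fry (adjusted p = 0.052). Of 14 tested, 0 rose and 2 fell, SLC2A1 (the glucose transporter GLUT1) from 27.8 ± 1.62 to 20.8 ± 1.69 RPKM and CD44 (a hyaluronan receptor) from 47.1 ± 1.90 to 39.0 ± 1.59 RPKM, and 8 were lower when adjusted over the list alone. The median log2 fold change was -0.19, and -0.13 after the GC correction. AXIN2, a feedback target of the pathway, was at 1.71 ± 0.14 RPKM in untreated and 1.62 ± 0.21 in treated cells (adjusted p = 0.792). CCND1, which encodes cyclin D1, was at 108 ± 8.75 and 89.7 ± 1.21 RPKM (adjusted p = 0.0722, but 0.0253 with library weights, 0.028 without untreated replicate 3 and 0.0468 without nanosilicate replicate 2), and MYC at 95.6 ± 3.17 and 96.5 ± 5.00 RPKM (adjusted p = 0.908). LEF1 was not among the listed genes. Of 29 genes of the β-catenin complex and Wnt signal transduction 0 passed the test over all genes (limma) and 1 was lower when adjusted over the list alone. CTNNB1, which encodes β-catenin itself, was at 320.5 ± 8.45 RPKM in untreated and 322 ± 25.8 in treated cells. Of 18 Wnt ligands, receptors and secreted regulators, 2 fell, and 4 were lower when adjusted over the list alone. The 2 were the secreted Wnt enhancer RSPO3 (3.04 ± 0.12 to 1.97 ± 0.24 RPKM) and the receptor FZD8 (16.7 ± 2.50 to 12.1 ± 0.25 RPKM). DKK3 and the Wnt inhibitor DKK1, secreted regulators of the same list, did not pass. They were at 211 ± 4.2 and 180 ± 6.9 RPKM (adjusted p = 0.0518) and at 98.3 ± 5.7 and 79.5 ± 7.7 RPKM (adjusted p = 0.068). The list thus mixes genes of opposite action. Of its 18 log2 fold changes 14 were negative, with a median of -0.043. For this list camera gave an adjusted p of 0.00259, and 0.258 with an estimated correlation. The fry adjusted p was 0.00344, and 0.0463 after the GC correction. FZD8, with a coding GC content of 70.9%, lost its call after the GC correction (log2 fold change from -0.43 ± 0.09 to -0.15 ± 0.05, SE, adjusted p = 0.191).

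Of 41 angiogenesis and tip-cell genes, 0 rose and 7 fell, among them COL4A1 and COL4A2, which the matrix and basement membrane list also counts. Adjusted over the list alone, 14 were lower. The median log2 fold change was -0.10, and -0.05 after the GC correction (camera adjusted p = 1.68e-06, adjusted p = 0.311 with an estimated correlation). ESM1, a proteoglycan of sprouting tip cells, fell from 230 ± 17.2 to 162 ± 9.92 RPKM, and ANGPTL4, a secreted lipase inhibitor, fell from 59.0 ± 2.38 to 42.2 ± 2.58 RPKM. CXCR4, a chemokine receptor of tip cells, fell from 136 ± 11.5 to 102 ± 5.69 RPKM. PDGFB, which recruits pericytes, fell from 99.7 ± 6.76 to 73.5 ± 7.55 RPKM but did not pass after the GC correction (adjusted p = 0.0589), where its log2 fold change was -0.37 ± 0.08 against -0.44 ± 0.08 before (SE) and 4 members of the list were lower. VEGFA was at 5.45 ± 0.40 and 5.2 ± 0.20 RPKM (adjusted p = 0.68), its receptor KDR at 129 ± 6.63 and 133 ± 3.48 RPKM (adjusted p = 0.691), and ANGPT2 at 130 ± 8.23 and 118 ± 20.4 RPKM (adjusted p = 0.47).

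Of 26 endothelial identity genes 1 fell, LYL1, a transcription factor with a coding GC content of 70%, and its call ended after the GC correction (log2 fold change from -0.38 ± 0.06 to -0.13 ± 0.05, SE, adjusted p = 0.257). The list was lower by camera (adjusted p = 0.00327, adjusted p = 0.42 with an estimated correlation), and 2 members were lower when adjusted over the list alone. The list call ended after the GC correction (camera adjusted p = 0.167, median log2 fold change from -0.08 to -0.018). The junction proteins PECAM1 (1443 ± 57.1 and 1397 ± 51.2 RPKM) and CDH5 (561 ± 27.7 and 503 ± 10.6 RPKM) did not pass, nor did the nitric oxide synthase NOS3 (31.3 ± 1.29 and 30.1 ± 2.94 RPKM). Of 20 Notch and arterial genes 2 fell, CXCR4 and NRARP, with 4 lower when adjusted over the list alone (camera adjusted p = 0.0145, adjusted p = 0.663 with an estimated correlation). This list call also ended after the GC correction (camera adjusted p = 0.239), with a median log2 fold change of 0.02 against -0.03 before. Of 15 vasoactive and shear-responsive genes 3 fell, among them PLAT (tissue plasminogen activator) and THBD (thrombomodulin), with 7 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00154, adjusted p = 0.278 with an estimated correlation). THBD did not pass after the GC correction (log2 fold change from -0.59 ± 0.12 to -0.38 ± 0.09, SE, adjusted p = 0.0832).

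Of 29 genes of the NRF2 oxidative stress response, 0 rose and 1 fell, MAFF, and the list did not stand apart from other genes (median log2 fold change 0.03, camera adjusted p = 0.487). Adjusted over the list alone, 2 were higher and 1 lower. HMOX1, the inducible heme oxygenase, was at 31.1 ± 2.31 RPKM in untreated and 38.9 ± 2.44 in treated cells, with no overlap between the groups and an adjusted p of 0.0531, which was 0.0273 after the GC correction. PIR, an iron-binding nuclear protein, was at 171 ± 5.90 and 204 ± 10.3 RPKM (adjusted p = 0.0518), and the quinone reductase NQO1 at 126 ± 7.15 and 129 ± 6.79 RPKM (adjusted p = 0.841). Of 25 ROS-producing and antioxidant enzymes, UCP2 rose and CYBA, a subunit of NADPH oxidase, fell from 56.1 ± 9.30 to 34.5 ± 1.86 RPKM (adjusted p = 0.0236). Adjusted over the list alone, 2 rose and 2 fell, and camera gave an adjusted p of 0.205.

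Genes of the TGF-β and BMP response and mesenchymal transition were lower as a list at the preset correlation (camera adjusted p = 1.17e-08). They were also lower with fry (adjusted p = 0.046), but not by camera with an estimated correlation (adjusted p = 0.258). Of 32 tested, 0 rose and 7 fell, among them INHBA, TAGLN and TGFB2, and 13 were lower and 1 higher when adjusted over the list alone. The median log2 fold change was -0.14 and -0.11 after the GC correction. Of 35 matrix and basement membrane genes 7 fell, including COL12A1, the short-chain collagen COL8A1 (39.5 ± 1.23 to 27.5 ± 3.19 RPKM) and the collagen lysyl hydroxylases PLOD2 and PLOD1, and 16 were lower when adjusted over the list alone (camera adjusted p = 5.35e-08, adjusted p = 0.278 with an estimated correlation). Of 20 YAP/TAZ targets 2 fell, TGFB2 and ANKRD1 (348 ± 4.98 to 258 ± 37.7 RPKM), and 12 were lower when adjusted over the list alone (camera adjusted p = 1.13e-06, adjusted p = 0.278 with an estimated correlation). CTGF and CYR61, secreted YAP/TAZ target proteins, were at 913 ± 73.3 and 731 ± 71.6 RPKM and at 495.5 ± 31.9 and 394 ± 40.7 RPKM (adjusted p = 0.0799 and 0.066). Of 25 matrix proteases and inhibitors 2 fell, among them PLAT, and 7 were lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00546, adjusted p = 0.278 with an estimated correlation).

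**Figure D3:**
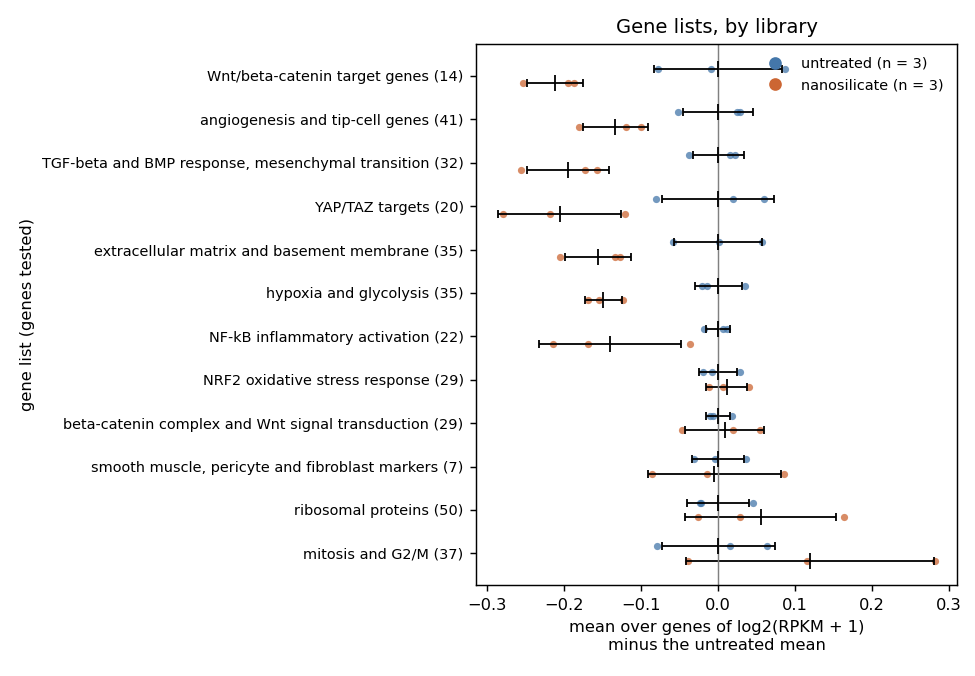
Mean over the tested genes of each list of log2(RPKM + 1) minus the gene's untreated mean (x axis, log2 units), for 12 lists with the number of genes in brackets (y axis); points are libraries, and black marks give the group mean with its SD. For TGF-β and BMP response genes the treated libraries sit at -0.16, -0.17 and -0.26, below all 3 untreated ones, and for NRF2 genes the groups overlap.

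Of 35 hypoxia and glycolysis genes 2 fell, the lactate exporter SLC16A3 (86.5 ± 5.76 to 56.3 ± 4.17 RPKM) and SLC2A1, and 14 were lower when adjusted over the list alone. This list had the smallest camera p (adjusted p = 5.4e-10, adjusted p = 0.258 with an estimated correlation), with a median log2 fold change of -0.14. Of 22 genes of NF-κB inflammatory activation 3 fell, the pattern recognition protein PTX3 (401 ± 14.8 to 292 ± 25.4 RPKM), the adhesion receptor SELP (8.67 ± 0.32 to 6.40 ± 0.34 RPKM) and the chemokine CXCL2 (12.8 ± 0.45 to 8.72 ± 1.31 RPKM), with 5 lower when adjusted over the list alone (camera adjusted p = 0.000158, adjusted p = 0.278 with an estimated correlation). Of 29 p53 targets and senescence genes 2 fell, the stress cytokine GDF15 (160 ± 24.4 to 103 ± 5.58 RPKM) and the cell cycle inhibitor CDKN1A (217 ± 8.65 to 167 ± 15.9 RPKM), and 8 were lower when adjusted over the list alone (camera adjusted p = 0.000954, adjusted p = 0.278 with an estimated correlation). CDKN1A did not pass after the GC correction (log2 fold change from -0.38 ± 0.07 to -0.28 ± 0.06, SE, adjusted p = 0.0578).

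Markers of other cell types were examined beside these lists. Of 7 smooth muscle, pericyte and fibroblast markers tested, from 18 fixed, 0 passed in limma's test. Their log2 fold changes ran from -0.19 for ACTA2 to 0.27 for THY1, with a median of -0.013. Of 4 epithelial markers (from 12 fixed), 1 leukocyte marker (CD68, from 18) and 2 osteogenic and chondrogenic genes (BGLAP and BMP2, from 15), 0 passed. The keratin KRT7, which fell, is not in the epithelial list. Adjusted over the list alone, 0 members of these 4 lists passed either. Of 6 lymphatic endothelial markers LYVE1 rose, the single member also past the threshold when adjusted over the list alone, and MMRN1, also of this list, was at 940 ± 58.7 and 1003 ± 78.3 RPKM (adjusted p = 0.487).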

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

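The GC, GC and length, GC with block, and voom alternatives were chosen after seeing the data, and the rest before. The planned DESeq2 alternative was not run. The deposited unit is RPKM, and limma-voom on the recovered reads was added instead. Counts of higher and lower genes (21 and 108) went to 12 higher with median-of-ratios scaling, 9 and 56 with quantile normalization, 13 and 61 without a trend, 39 higher with robust moderation, and 471 and 571 with library weights. They were 67 lower with the GC correction, 71 lower with GC and length, 36 higher with voom, 0 and 8 at an adjusted p of 0.01 in limma (2138 genes had an unadjusted p under 0.05), and 1 and 18 with a fold of at least 1.5. The stricter thresholds lower the counts by construction. Without 1 library, counts ran from 1 to 351 higher and from 16 to 430 lower, fewest without nanosilicate replicate 1 and most without nanosilicate replicate 2. For the others the cause was not tested. The adjusted p of the Wnt target list went from 1.13e-06 with camera to 0.258 with an estimated correlation and 0.052 with fry. That of the angiogenesis list went from 1.68e-06 to 0.311 and 0.0803. With the GC correction as well, these were 0.214 and 0.0775 for the Wnt targets and 0.319 and 0.131 for angiogenesis. With camera at the preset correlation, both stayed lower and past the threshold in the other alternatives run. The NRF2 list, not past the threshold in any test for a shift in 1 direction, changed direction with library weights (adjusted p = 0.84) and without nanosilicate replicate 3 (left-out range 0.129 to 0.824). The mixed form of fry, which counts changes in both directions, gave it an adjusted p of 0.0195. It gave 0.0147 for the smooth muscle, pericyte and fibroblast markers, of which 0 passed in limma. The 20 called genes named for size kept their direction in all 395 values and lost the call in 77. The rule that named them required no overlap between the groups. Leaving out a library, or another pseudocount, filter, moderation, weighting or block, could therefore not have reversed them. At an adjusted p of 0.05, KRT7, INHBA, TAGLN, AK4, LYVE1 and TGFB2 passed in every alternative fit that tested them (TGFB2 was below the filter at 5 RPKM), but LYVE1 and TGFB2 did not pass at 0.01. Of the uncalled fixed genes, HMOX1 passed in 8 of 20 fits (adjusted p from 0.00271 to 0.155) and CCND1 in 4 of 20 (0.023 to 0.239). The lowest values came with the replicate number as a block, for HMOX1 with the GC correction as well (0.00635 with the block alone).

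Reversals were limited to 7 uncalled genes besides that list, and the cause was not tested. With libraries left out, the log2 fold change ran from -0.10 to 0.015 for AXIN2, -0.034 to 0.071 for CTNNB1, -0.028 to 0.042 for MYC, -0.13 to 0.0083 for NOS3 and -0.022 to 0.062 for NQO1. With median-of-ratios scaling CTNNB1 was at -0.012 and MYC at -3e-04, and with library weights MYC was at -0.0095 and NQO1 at -0.029. With the GC correction, alone and with the block, CTNNB1 was at -0.019, VEGFA at 0.018 and NOS3 at 0.069. With GC and length, CTNNB1 was at -0.029, VEGFA at 0.021, KDR at -0.0064 and NOS3 at 0.048.

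The groups share replicate numbers, but the labels state no pairing, so the numbers were not a block in the main fit. The deviations of same-numbered libraries correlated at 0.05, 0.28 and 0.19, against -0.21 to 0.03 for differently numbered ones. Thus 6 of 6 libraries correlated best with their own number, a hint from the data and not the design. With the replicate number as a block, 141 genes were higher and 490 lower, and with the GC correction and the block 101 and 186. At the depth of these libraries, at least 45476807 reads, simulated 1.2-fold changes were recovered in 32% of genes.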

Other observations

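All tests of explanations in this part were chosen after the results were seen, except the test of depth.

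Of 37 mitosis and G2/M genes 0 passed in limma's test, although 35 had a positive log2 fold change, with a median of 0.12 (camera adjusted p = 0.00021, adjusted p = 0.663 with an estimated correlation). CDK1, the mitotic kinase, was at 58.4 ± 4.12 and 69.97 ± 8.70 RPKM, and TOP2A, a topoisomerase of dividing cells, at 30.4 ± 1.92 and 36.3 ± 3.93 RPKM. Of 43 DNA replication genes 0 passed (camera adjusted p = 0.169), nor did any of 50 ribosomal protein genes (0.169) or 3 histone genes (0.143). Adjusted over the list alone, 0 genes passed in the mitosis, replication and ribosomal lists and 1 histone gene was higher. Of 45 nuclear-encoded oxidative phosphorylation genes 1 fell, NDUFS7, a subunit of complex I (camera adjusted p = 0.487), whose call ended with the GC correction (log2 fold change from -0.34 ± 0.06 to -0.14 ± 0.05, SE, adjusted p = 0.211). Of 34 interferon response genes (camera adjusted p = 0.915) and 17 heat shock genes (0.653), 0 passed. Adjusted over the list alone, 4 oxidative phosphorylation genes and 1 interferon gene were lower, and 0 heat shock genes passed.

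Of 14 metallothionein and metal response genes 1 fell, MT2A, a metal-binding protein, from 1749 ± 79.4 to 1367 ± 41.1 RPKM (camera adjusted p = 0.0163 for the list, adjusted p = 0.278 with an estimated correlation). Of 30 unfolded protein and ATF4 response genes STC2, a secreted glycoprotein, fell from 30.6 ± 1.32 to 22.7 ± 1.74 RPKM (camera adjusted p = 0.00192, adjusted p = 0.568 with an estimated correlation). Of 26 immediate early genes DUSP1, a phosphatase of MAP kinases, fell from 51.3 ± 1.48 to 42.0 ± 1.95 RPKM (camera adjusted p = 1.9e-05, adjusted p = 0.311 with an estimated correlation), and did not pass after the GC correction (log2 fold change from -0.28 ± 0.05 to -0.21 ± 0.05, SE, adjusted p = 0.069). None of 38 lysosome and autophagy genes (camera adjusted p = 0.00972, adjusted p = 0.258 with an estimated correlation), 29 endocytosis genes (0.00528 and 0.469) or 27 cholesterol synthesis genes (0.0059 and 0.55) passed in limma's test. Of 31 integrin and migration genes RHOB, an endosomal small GTPase, fell from 461 ± 83.1 to 300.1 ± 36.5 RPKM (camera adjusted p = 0.169) and did not pass after the GC correction (log2 fold change from -0.61 ± 0.12 to -0.51 ± 0.11, SE, adjusted p = 0.0581), and of 26 junction genes CDH2, N-cadherin, fell from 30.9 ± 1.71 to 24.0 ± 0.88 RPKM (camera adjusted p = 0.102, adjusted p = 0.0412 after the GC correction and adjusted p = 0.574 after it with an estimated correlation). Adjusted over the list alone, 4 metal response genes were lower and 1 higher, 3 unfolded protein response, 9 immediate early, 2 cholesterol synthesis and 2 junction genes were lower, 4 integrin and migration genes were lower and 1 higher, and 0 lysosome or endocytosis genes passed.

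The genes that fell leaned to high GC content, and 1 of the 108 had no GC value. Of the 39 lower genes under 60% GC, 37 stayed past the threshold after the GC correction. Their median log2 fold change went from -0.41 to -0.43. Over all tested genes the median was above 0 in each group under 60% GC, from 0.095 under 40% to 0.003 at 55 to 60%. The GC trend thus did not lower these 39 genes, and the correction could not have brought them to 0. It leaves open library effects that do not follow coding GC. Of the 68 at 60% or more, 20 (29.4%) stayed past the threshold, and for the 48 that did not, the median went from -0.35 (median SE 0.07) to -0.23 (median SE 0.06), while the genes with an unadjusted p under 0.05 went from 2138 to 1747, and the parts of these in ending the calls were not separated. For these, library preparation and treatment cannot be told apart, because the GC slopes follow the groups and an exact test cannot go below p = 0.1 with 3 against 3. Thinning all libraries to 45476807 reads gave 113 lower genes, among them 95 of the 108. This argues against unequal counting noise as the source of the lower genes. RPKM is already scaled to library total, so thinning cannot test a library bias that goes with depth.

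A candidate explanation for the lower TGF-β, matrix and YAP/TAZ genes is a change within the endothelial cells after exposure, which is a hypothesis, since the pattern was found and tested on the same data. Of the 84 tested members of the 3 lists, 15 fell and 0 rose, with a median log2 fold change of -0.37 over these 15 and -0.14, -0.14 and -0.19 over all tested members of the TGF-β, matrix and YAP/TAZ lists. Fewer stromal cells would lower the markers that stromal cells supply, but which cells supplied them was not tested. Of 18 fixed stromal markers 7 could be tested. Their log2 fold changes ran from -0.19 (ACTA2 and COL3A1, the fibroblast collagen COL3A1 at 2.10 ± 0.17 and 1.73 ± 0.33 RPKM) to 0.27. The median was -0.013, and 0.07 for the 4 that are not in these lists. TAGLN, of contractile cells, fell (log2 fold change -0.73) but belongs to the pattern itself. The 7 markers thus did not fall as a set, but they cannot exclude a loss of stromal cells. After the GC correction the 15 fallen genes had a median of -0.38, and 11 stayed past the threshold. This argues against the trend with coding GC as their whole cause. Library effects that do not follow coding GC were not tested. A more crowded, less proliferating culture stays open, because the mitosis scores overlapped (-0.08 to 0.06 untreated, -0.039 to 0.28 treated) and cell density was not measured.

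With 10 distinct splits of the 6 libraries, no share under 0.05 can be reached. The real split gave 21 higher and 108 lower genes, and the other splits at most 0 in either direction, so 1 of the 10 gave as many higher genes and 1 of the 10 as many lower ones. For gene lists called by camera, the real split gave 20 and the highest other split 19, with 1 of the 10 splits reaching 20.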
